A study of Homo sapiens with 6 samples.

How the data were processed

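Total RNA from 6 samples of Caco-2 cells, grown to below confluence without treatment, was amplified, labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The groups follow the sample titles, with 2 arrays each of Ha-RAS transformed cells, Ki-RAS transformed cells and control cells. The samples of a group are biological replicates per the series' design text. How they were separated is not given in the sources used here. The p-values thus rest on the spread between these arrays, pooled over the groups and moderated with the spread of all probes tested.

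The deposited signal of each probe is a mean fluorescence intensity over its beads on a linear scale, per the file headers, with the spread between beads as a further intensity column, the number of beads, and a detection score that is near 1 for bright probes. The authors applied no normalization, per the series' design text, and used BeadStudio 1.5.13, per the submitters' processing notes. Whether background was subtracted is not given in the sources used here. The lowest signal on any array was 38.7, so the values look unsubtracted. The deposited table of the whole series holds the intensity values of the array files, with 0 differing cells. The detection score runs in steps of 1 over 775. The authors' differential expression analysis, with a custom error model, was not rerun.

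Each array held 24354 probes. Of these, 4 are named for bacterial genes (lysA, pheA, thrB and trpF) and were left out before background correction. The other 24350 are named by a GI number with a suffix. By the manufacturer's convention the suffix S marks a single transcript (19254 probes), A all isoforms of a transcript (2182) and I 1 of several isoforms (2914). No probe ID matched the RefSeq table of gene symbols for GRCh38.p14 (0 matches), and the files do not pair IDs with gene names. The 22 gene lists and the 5 genes chosen in advance could therefore not be measured, and no gene list was tested. No transcript could be used to check the labels.

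Detection p was taken as 1 minus the detection score. Background was corrected with the nec function of limma 3.58.1 (R 4.3.3), which infers the mean and SD of negative controls from the detection p, with an offset of 16. The values were then log2 transformed and quantile normalized between arrays. The inferred background means were 62.1 to 69.8 intensity units, with SDs of 6.88 to 7.56. Probes with detection p at or below 0.01 on both arrays of at least 1 group were tested (10848). Per probe, lmFit was fitted over all 6 arrays with 3 group means and no covariate (3 residual degrees of freedom, 7.1 prior degrees of freedom), followed by contrasts and eBayes, two-sided, with Benjamini-Hochberg adjustment within each of the 3 comparisons. A probe is called changed at adjusted p below 0.05. The number of arrays limits the precision.

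The groups, the tests, the rule for named probes and the alternatives were fixed before the data were examined. The rule was written for probes with a gene name, and took the 10 highest and the 10 lowest fold changes per comparison among called probes detected on both arrays of the brighter group. Without gene names, it was applied to IDs and shortened to the 2 highest and the 2 lowest per comparison, and to 2 per direction for the shared and the opposite calls, ranked by the smaller of both changes. Together these are 15 probes. Where no array of the dimmer group detected a probe, the fold is a bound. It is the mean of the brighter group over the mean of, per array, the higher of the lowest normalized signal among detected probes and the probe's own signal, and it is written as "at least". Where both groups were undetected no fold is given. The bounds and folds depend on the background correction. The offset of 16 makes the fold changes of dim probes smaller.

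The overlap of calls was set beside independent lists of the same sizes and beside 100 simulated sets of unchanged groups that shared controls. Alternatives covered the background correction, the normalization between arrays, the filter on dim probes, the spread estimate, the arrays in the fit, the replicate letter as a block, each array left out and the threshold. The files name no slide, so the slide could not be used as a block. Direct comparison of line sets, the fold thresholds on them and the direction of isoform-specific probes were added after the data were seen.

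The procedure was tested on simulated data for the Ha-RAS against control comparison, with 24350 probes of which 200 were changed. The 200 were drawn from probes detected on all 6 arrays, so their recovery does not extend to dimmer probes. The spread of every simulated probe was also drawn from the spread estimates of such probes, and background noise was added. At 1.5-fold 2 of 67 changed probes were called, at 2-fold 49 of 67 and at 4-fold 66 of 66. The median estimated log2 changes were 0.56, 0.92 and 1.75, each smaller than simulated. Of 146 calls, 29 were unchanged probes, above the nominal rate. Their median log2 level was 4.9, against 7.08 for all tested probes. On the same simulated arrays 0 of 92 calls were unchanged probes with no filter, and 10 of 129 among probes detected on all 6 arrays. With 5854 changed probes, 76% of those tested were recovered, and 502 of 4825 calls (10.4%) were unchanged probes, against 239 of 3843 (6.22%) with no filter and 333 of 4160 (8%) among probes detected on all 6 arrays. Figures were drawn with matplotlib 3.10.9.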

Results

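Gene expression was measured in 3 lines of Caco-2 cells, an established human colon adenocarcinoma line that forms an epithelial layer resembling intestinal absorptive cells. One line was transformed with Ha-RAS and one with Ki-RAS. These are isoforms of the RAS family of small GTPases, which relay growth signals from receptors at the cell membrane. The parental Caco-2 cells served as control. The labels describe the Ki-RAS cells, and 1 of the 2 Ha-RAS samples, as fast growing, and they add an epithelial-to-mesenchymal transition phenotype for that Ha-RAS sample. Each line was profiled on 2 Illumina bead arrays, giving 6 arrays in 3 groups of 2, and the design text calls the paired samples of a line biological replicates. Each RAS isoform is represented by 1 cell line, so a difference between groups is a difference between lines, and the spread between replicates is the spread between samples of a line.

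Each array reported 24350 probes named by a GI sequence number, of which 9245 to 10192 were detected per array. The Ha-RAS arrays detected 10092 and 10192 probes, the Ki-RAS arrays 9423 and 9528, and the control arrays 9245 and 9702. The median number of beads behind a signal was 41 or 42 on every array. The median signal of detected probes was 2.86 to 3.64 times that of undetected ones. A total of 10848 probes were detected on both arrays of at least 1 line and were tested. Over these probes the replicates of a line correlated at r = 0.987 for control, 0.993 for Ha-RAS and 0.989 for Ki-RAS, across probes, which are not independent replicates. Arrays of different lines correlated between 0.814 and 0.834. No probe ID could be paired with a gene symbol from the tables used here, so probes are given by their IDs. Fold changes are differences of mean normalized log2 intensity, with n = 2 arrays per line, and adjusted p-values are those of limma.

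The first comparison addressed which transcripts differ between Ha-RAS transformed cells and control cells. Probes GI_4507894-S and GI_4758505-S had the highest fitted log2 differences. The log2 intensity of GI_4507894-S was 12.74 ± 0.066 (SD, n = 2) in Ha-RAS cells and 4.48 ± 0.021 in control cells, where neither array detected it. The rise was at least 187-fold (adjusted p = 3.77e-10). Probe GI_4758505-S rose from 4.96 ± 0.69 to 13.10 ± 0.022, a 283-fold difference (log2 difference 8.15 ± 0.26 SE, adjusted p = 4.36e-09), and 1 of the 2 control arrays detected it. The order of these 2 probes depended on the background and on the arrays used. Their fitted folds were 101 and 111 without background correction, and 320 and 410 without control replicate A. The lowest fitted differences were those of GI_4557320-S and GI_9845517-S, which were bright in control cells and undetected on both Ha-RAS arrays. GI_4557320-S fell from 12.97 ± 0.15 to 4.67 ± 0.10, or at least 249-fold (adjusted p = 3.77e-10), where the fitted fold without background correction was 109. GI_9845517-S fell from 12.21 ± 0.062 to 4.34 ± 0.042, or at least 147-fold (adjusted p = 3.77e-10), where the fitted fold without background correction was 78.3. These bounds hold for the background correction used here.

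In all, 5854 of the 10848 probes (53.96%) differed between Ha-RAS and control at the adjusted p threshold, with 3104 higher and 2750 lower in Ha-RAS cells. The majority direction depended on the normalization, with 2862 higher and 3032 lower under cyclic loess. The median size of a called change was 0.92 on the log2 scale, against a median standard error of 0.17. Changes of at least 2-fold were found for 1262 higher and 1332 lower probes, and changes of at least 16-fold for 71 higher and 88 lower probes. The 16-fold counts were 24 and 27 without background correction, and 6 and 14 on probes detected on all 6 arrays. The values of the 2 Ha-RAS arrays did not overlap those of the 2 control arrays for 76.97% of probes, where chance gives 33.33%. With the added requirement of a 2-fold change the number of calls was 2594, or 1519 without background correction. In simulated data for this comparison with as many changed probes as were called, 10.4% of all calls were unchanged probes. Of the simulated calls with at least 2-fold change 0.411% were, so small changes were the less certain part there. The simulated spread came from probes detected on all 6 arrays, with background noise added. The simulation thus does not settle how certain large changes of dim probes are.

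The second comparison set the Ki-RAS transformed cells against the same control cells. Probe GI_11995467-S rose from a log2 intensity of 5.68 ± 1.1 (SD, n = 2) in control cells to 12.96 ± 0.20 in Ki-RAS cells, a 156-fold difference (log2 difference 7.28 ± 0.39 SE, adjusted p = 1.52e-07). It was detected on 1 of the 2 control arrays, and the fold was 279 without control replicate A, 90.6 without control replicate B and 76.2 without background correction. Probe GI_42476152-S rose from 4.57 ± 0.42, below detection on both control arrays, to 11.62 ± 0.16, or at least 85.8-fold (adjusted p = 3.58e-09), where the fitted fold without background correction was 47.6. GI_4557320-S had the lowest fitted difference in this comparison too, falling from 12.97 ± 0.15 to 4.66 ± 0.12, or at least 220-fold (adjusted p = 7.39e-10). GI_16507959-S fell from 12.19 ± 0.098 to 4.35 ± 0.029, or at least 129-fold (adjusted p = 7.39e-10). Neither of these 2 probes was detected on a Ki-RAS array, and without background correction their fitted folds were 110 and 76.7. GI_4507894-S, which was higher in Ha-RAS cells, was undetected on both Ki-RAS arrays and on both control arrays.

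Of the 10848 probes, 5982 (55.14%) differed between Ki-RAS and control, with 3027 higher and 2955 lower in Ki-RAS cells. The median size of a called change was again 0.92 on the log2 scale. At least 2-fold changes numbered 1271 higher and 1359 lower, and at least 16-fold changes 60 higher and 69 lower. The 16-fold counts were 20 and 23 without background correction, and 6 and 6 on probes detected on all 6 arrays. The values of the 2 groups did not overlap for 75.99% of probes, against 33.33% by chance. With the added requirement of a 2-fold change the number of calls was 2630, or 1449 without background correction.

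The third comparison tested the difference between the Ha-RAS and Ki-RAS cells directly, without the control arrays entering the contrast. GI_4507894-S was higher in Ha-RAS cells by at least 188-fold over its Ki-RAS level, which neither array detected (adjusted p = 1.06e-09). GI_9845514-I, a probe for 1 of several transcript isoforms, was at 12.84 ± 0.032 (SD, n = 2) in Ha-RAS and 5.20 ± 0.049 in Ki-RAS cells. The difference was 200-fold (adjusted p = 2.06e-08), with 1 of the 2 Ki-RAS arrays detecting the probe, and the control level lay between them at 7.93 ± 0.85. In the other direction, GI_21536453-S was at 4.75 ± 0.30 in Ha-RAS and 12.57 ± 0.24 in Ki-RAS cells, at least 188-fold lower in Ha-RAS (adjusted p = 1.79e-09). Its control level of 11.63 ± 0.22 lay near that of Ki-RAS cells, although the log2 difference of 0.93 between these also passed the test (adjusted p = 0.00271). GI_19913425-S was at 4.59 ± 0.22 in Ha-RAS and 11.99 ± 0.06 in Ki-RAS cells, at least 126-fold lower in Ha-RAS (adjusted p = 3.15e-09). Its control level was 5.75 ± 0.41. Without background correction the fitted folds of GI_4507894-S, GI_9845514-I, GI_21536453-S and GI_19913425-S were 92.3, 85, 81.2 and 58.

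**Figure D1:**
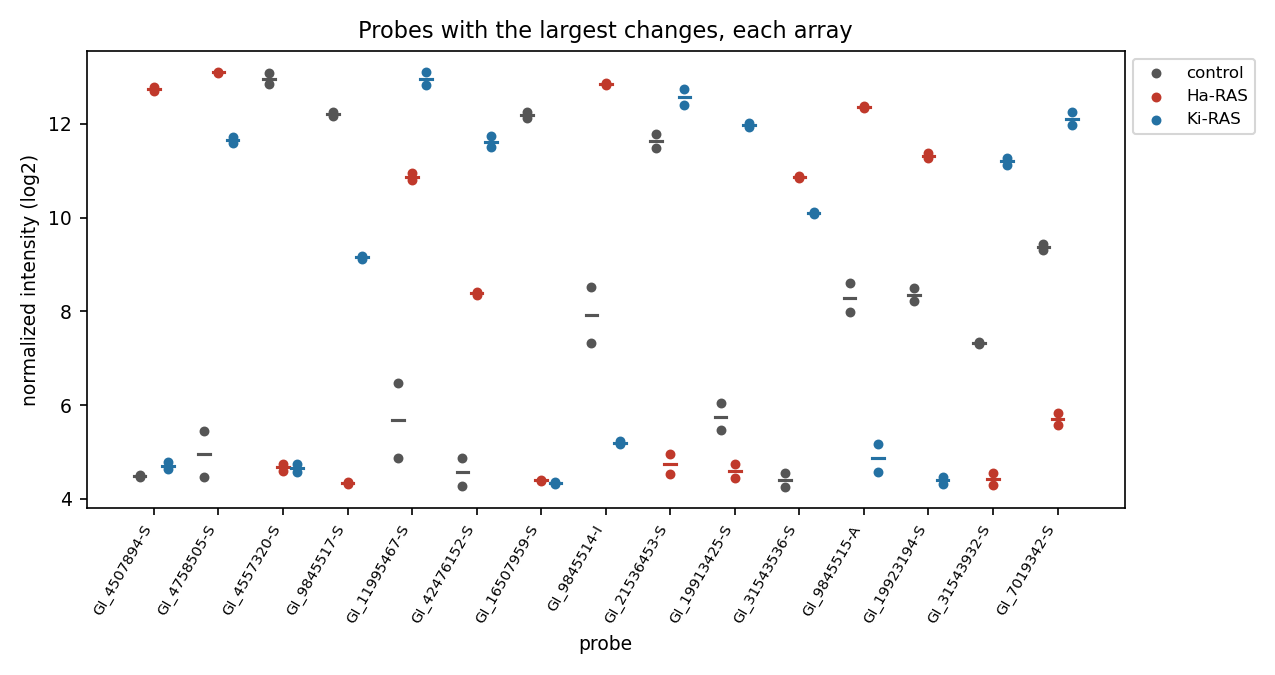
Normalized log2 intensity (vertical axis) of the 15 named probes (horizontal axis), with 1 point per array, 2 arrays per line, and a short bar at the mean of each line. GI_4507894-S stands near 12.74 in Ha-RAS cells alone, while GI_4557320-S stands near 12.97 in control cells alone.

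Between the 2 RAS lines 6473 probes (59.67%) differed, 3428 higher and 3045 lower in Ha-RAS cells. The majority direction depended on the normalization, with 3099 higher and 3303 lower under a common median and 3212 and 3292 under cyclic loess. The count of 6473 was above both counts against control. Changes of at least 2-fold were found for 1476 probes higher and 1394 lower in Ha-RAS, and changes of at least 16-fold for 57 higher and 86 lower. Without background correction the 16-fold counts were 23 higher and 20 lower, so that the larger share turned, and on probes detected on all 6 arrays they were 4 and 22. The values of the 2 RAS lines did not overlap for 80.73% of probes, against 33.33% by chance. With the added requirement of a 2-fold change the number of calls was 2870, or 1599 without background correction. Across the 3 comparisons 8887 probes (81.92%) were called at least once and 1946 in all 3.

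The calls of both RAS lines against control were then set side by side. GI_4758505-S and GI_31543536-S had the highest fitted differences in both lines, by the smaller of both. GI_4758505-S was 283-fold higher in Ha-RAS and 104-fold higher in Ki-RAS cells, and the Ha-RAS level was the higher by a log2 difference of 1.45 ± 0.26 SE (adjusted p = 0.000878). Only 1 of the 2 control arrays detected this probe. With 1 array left out its folds ran from 205 to 410 in Ha-RAS and from 74.4 to 151 in Ki-RAS cells. GI_31543536-S was undetected in control cells at 4.40 ± 0.22 (SD, n = 2) and reached 10.87 ± 0.033 in Ha-RAS and 10.10 ± 0.032 in Ki-RAS cells, or at least 51-fold and at least 30-fold higher (adjusted p = 1.41e-09 and 3.25e-09). Without background correction the fitted folds of GI_4758505-S were 111 and 41.1, and those of GI_31543536-S 31.1 and 18.6. GI_4557320-S and GI_16507959-S had the lowest fitted differences in both lines, and neither was detected on any of the RAS arrays. GI_16507959-S fell at least 146-fold in Ha-RAS and at least 129-fold in Ki-RAS cells. Both lines called 1283 probes higher and 1483 lower than control, together 2766 probes in the same direction.

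Independent lists of these sizes would share 866 probes in the higher and 749 in the lower direction. An excess was also found with each other line as the shared reference. It was 3275 probes against 1753 for independent lists with Ha-RAS, and 3381 against 1784 with Ki-RAS. The excess was thus not particular to the control as reference. In 100 simulated sets of unchanged groups against shared controls, the highest number of probes called in the same direction was 1. Unchanged groups give almost no calls after adjustment, so this number does not show how much of the overlap comes from the shared controls. Part of the excess over independent lists may come from the control arrays that both comparisons share, which were not split between the comparisons. The fold changes of the 2 lines correlated at r = 0.488 across probes with a covariance of 0.638. Simulated unchanged groups gave a mean r of 0.50, a mean covariance of 0.0164 and a highest covariance of 0.0177. These values argue against replicate noise of the shared control arrays as the source of most of the covariance. They do not give its part in the number of shared calls. On the 7610 probes detected on all 6 arrays, 1823 probes were called in the same direction.

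**Figure D2:**
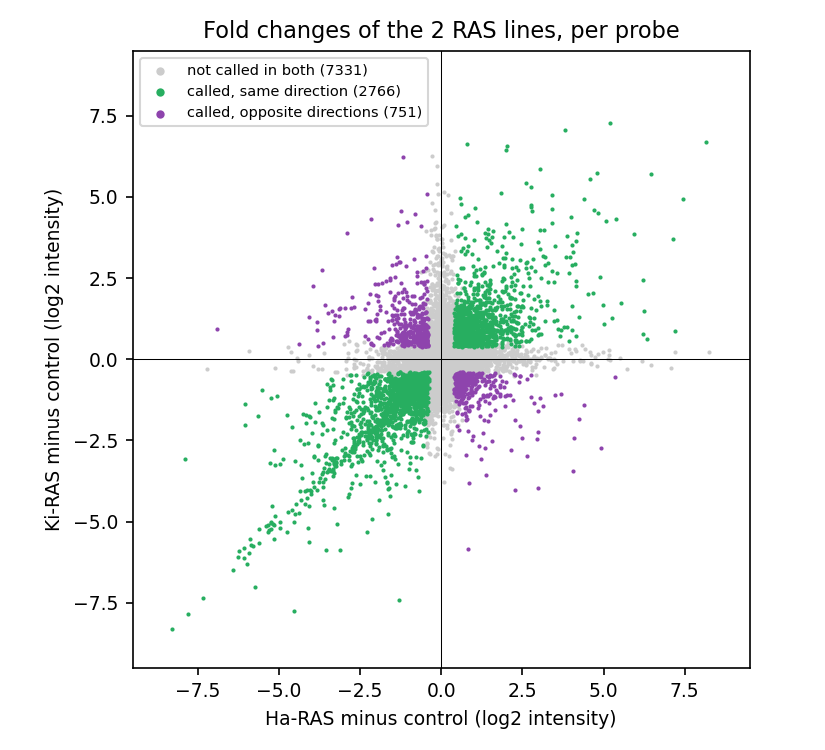
Log2 fold change against control of each of the 10848 tested probes in Ha-RAS cells (horizontal axis) and in Ki-RAS cells (vertical axis), each point a probe. The 2766 probes called in the same direction in both lines fill the lower left and upper right, and the 751 called in opposite directions the other quadrants.

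Probes that rose in one RAS line and fell in the other numbered 751. Of these, 355 were higher in Ha-RAS and lower in Ki-RAS cells, and 396 were lower in Ha-RAS and higher in Ki-RAS cells. GI_9845515-A, a probe for all isoforms of its transcript, was at 8.29 ± 0.44 (SD, n = 2) in control cells, 12.36 ± 0.028 in Ha-RAS and 4.87 ± 0.42 in Ki-RAS cells, where it was undetected (adjusted p = 2.95e-07 and 1.11e-06 against control). GI_19923194-S was at 8.35 ± 0.20 in control, 11.33 ± 0.061 in Ha-RAS and 4.40 ± 0.11 in Ki-RAS cells, where it was undetected (adjusted p = 1.59e-07 and 2.46e-08). GI_31543932-S went the other way, from 7.32 ± 0.04 in control to 4.41 ± 0.18 in Ha-RAS, where it was undetected, and 11.20 ± 0.11 in Ki-RAS cells (adjusted p = 1.71e-07 and 2.46e-08). GI_7019342-S was at 9.37 ± 0.088 in control, 5.70 ± 0.19 in Ha-RAS and 12.11 ± 0.19 in Ki-RAS cells (adjusted p = 4.76e-08 and 4.31e-07). Independent lists would give 1613 probes called in opposite directions, but these comparisons share the control arrays. With Ha-RAS or Ki-RAS as the shared reference the opposite calls were 599 and 596, against 1740 and 1786 for independent lists.

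The same count was made with each line in turn as the one set apart from the other lines. The control differed in 1 direction from both RAS lines for 2766 probes. Ha-RAS cells differed in 1 direction from control and Ki-RAS cells for 3275 probes, and Ki-RAS cells from control and Ha-RAS cells for 3381 probes. Of the 5854 Ha-RAS calls against control, 3275 (55.94%) were called in the same sense against Ki-RAS as well, and 1980 did not differ at the threshold between the RAS lines. A probe called in all 3 comparisons counts for more than 1 line. Among changes of at least 4-fold the numbers were close, at 311 for control, 310 for Ha-RAS and 281 for Ki-RAS. Among changes of at least 8-fold the order was the other way round, with 136 probes setting the control apart, 112 Ha-RAS and 88 Ki-RAS. Of the 136, 104 were lower in both RAS lines. Without background correction the 8-fold numbers were 51, 50 and 24. On the probes detected on all 6 arrays, which leave out transcripts lost from a line, they were 11, 17 and 8.

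**Figure D3:**
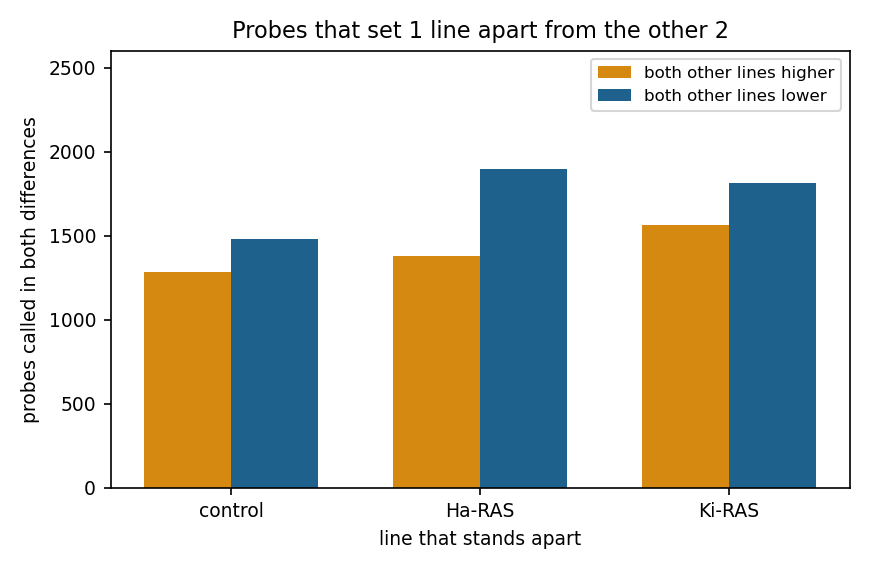
Number of probes (vertical axis) called in the same direction in both differences between a line and the other 2 lines, for each line (horizontal axis), with bars for probes higher and lower in the other lines. The control is set apart by 1283 and 1483 probes, Ha-RAS by 1381 and 1894, and Ki-RAS by 1566 and 1815.

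Detection gave a view that does not rest on a fold change. It comes from the same signals as the calls, so agreement between them is not separate support. A group of 298 probes was detected on both arrays of each RAS line and on neither control array, and 255 of them were called in both comparisons. In the reverse pattern, 322 probes were detected on both control arrays and on no RAS array, and 316 of them were called in both. Detection in Ha-RAS cells alone was found for 544 probes, of which 426 were called against both other lines, and in Ki-RAS cells alone for 317, of which 309 were. The other 2 patterns were 316 probes detected in control and Ha-RAS but not Ki-RAS cells and 193 detected in control and Ki-RAS but not Ha-RAS cells. All 3 lines detected 7610 probes, 70.15% of those tested.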

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

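The tests behind the calls were planned, and the count of lines per isoform was added after the result was seen. A total of 751 probes were called against control in opposite directions in the 2 RAS lines. The difference between the lines is then larger than either change, so its test passes for each by construction. Against control, GI_9845515-A was 16.7-fold higher in Ha-RAS and at least 8.61-fold lower in Ki-RAS cells, where no array detected it. GI_31543932-S was at least 4.97-fold lower in Ha-RAS cells, where no array detected it, and 14.7-fold higher in Ki-RAS cells. Without background correction the fitted folds were 14.5 and 4.67 for GI_9845515-A and 3.31 and 11.4 for GI_31543932-S. Independent lists of these sizes would hold 1613 such probes, but these comparisons share the control arrays. With Ha-RAS or Ki-RAS as the shared reference the opposite calls were 599 and 596, so 751 was the highest of the 3 counts. The number of lines per isoform is 1, so a difference between isoforms and a difference between individual lines cannot be told apart.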

How the results depend on the processing

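The named probes kept their direction under each alternative in which they were tested, in 338 values over 15 probes. Part of these values could not turn. The filters, the spread estimate, the fit on only the arrays compared and the replicate block leave the fold of a probe as it was. Only the background, the normalization and the left-out arrays could change a direction. In the fits on 2 arrays per line the named probes also kept their side of the threshold. The values cover only the differences for which each probe was chosen. These probes were picked for the largest changes, so their stability does not extend to the other calls. On probes detected on all 6 arrays, GI_7019342-S was the only named probe left. Their fold sizes depended on the background correction, and the 24 fitted folds were 1.06 to 3.03 times those without it. Leaving out 1 array moved 1 of the 24 by over 1.5 times, that of GI_11995467-S in Ki-RAS cells (156, with 90.6 to 279). The calls were 5854 for Ha-RAS against control (3959 to 6007 under other backgrounds, normalizations, filters, spread estimates and array sets), 5982 for Ki-RAS against control (4156 to 6129) and 6473 for Ha-RAS against Ki-RAS (4470 to 6605). The lowest of each came from testing only the 7610 probes detected on all 6 arrays, where the calls in the same direction were 1823 in place of 2766. Fewer probes are tested there, and transcripts lost from a line are left out. With a fold change of at least 2 required, the calls were 2594, 2630 and 2870, and 1021 in the same direction, since this removes the smaller changes. Without background correction these numbers were 1519, 1449, 1599 and 576, with normexp fitted to the signals alone 1530, 1465, 1609 and 584, and on the probes detected on all 6 arrays 1360, 1382, 1643 and 438. An adjusted p threshold of 0.01 gave 4284, 4471, 5051 and 1888. Leaving out each array in turn gave 4378 to 5827, 4960 to 5659, 5134 to 6623 and 2192 to 2569, where the lone array of a group is assumed to vary like the other groups. The upper ends for Ha-RAS against control and for Ha-RAS against Ki-RAS came from leaving out an array of the line outside the comparison. The replicate letters are shared between groups, but nothing says that they mark a batch. The deviations of same-letter arrays correlated at -0.177, 0.104 and -0.173. With the replicate block the calls were 5681, 5791, 6331 and 2656. The share of calls that were higher ranged over 48.6 to 53.1%, 50.1 to 55.3% and 48.4 to 53.3% across backgrounds, normalizations, filters and fits. The majority direction turned with the normalization and with the fold threshold. With a fold change of at least 2 required, it turned for both RAS lines against control. The counts there were 1262 higher and 1332 lower in Ha-RAS cells, and 1271 and 1359 in Ki-RAS cells. For Ha-RAS against control it also turned with cyclic loess (2862 higher, 3032 lower). For Ha-RAS against Ki-RAS it turned with a common median (3099 and 3303) and with cyclic loess (3212 and 3292). The correlation of the fold changes of the RAS lines, checked after the data were seen, was 0.414 on probes detected on all 6 arrays. The gene list tests, the value table and the slide block were not run, because no gene names could be matched, the table equals the array files and no slide is named. Signals lie close to background for many probes, with median detected signals 2.86 to 3.64 times the undetected ones, and a fold against a line in which no array detected the probe is a bound.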

Other observations

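The tests of shared-control noise, of quantile normalization and dim probes for the distances between lines, of a common response (for changes of any size and of at least 8-fold), of divergence of individual lines, of several probes per gene and of array sensitivity were chosen only after the results were seen, as were the patterns themselves. The tests of quantile normalization and of low level for the isoform-specific probes had their criteria set before their results were seen. The criterion first set for the distances looked in 1 direction only and was replaced by the range of the correlations.

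Probes that set the control apart from both RAS lines by large amounts were mostly losses. At 16-fold or more, 50 of the 62 such probes were lower in both RAS lines, as GI_4557320-S and GI_16507959-S were, while 12 were higher. For Ki-RAS cells apart from the other lines, 29 of 32 were lower in the other lines, so here gains of Ki-RAS cells alone dominated. For Ha-RAS cells the numbers were 35 of 53. Without background correction the totals of 62, 32 and 53 became 21, 9 and 15, of which 17, 7 and 12 were lower in the other lines, and on probes detected on all 6 arrays they were 4, 2 and 4, of which 3, 2 and 1 were. The split thus turned for Ha-RAS cells on those probes, also at 8-fold, with 5 of 17 lower in the other lines. In control cells alone, 90 probes were detected with a bound of at least 4-fold against both RAS lines, against 40 probes detected in both RAS lines but not in control cells with such a bound. The matching numbers were 61 in Ha-RAS cells alone against 41 in control and Ki-RAS but not Ha-RAS cells. For Ki-RAS cells alone they were 59, against 16 in control and Ha-RAS but not Ki-RAS cells. The excess was thus found for each line and was not particular to the control. The 4 probes named for bacterial genes were not detected on any array, with signals of 62.1 to 82.3 and a lowest detection p of 0.0103.

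The 3 lines were about equally far apart, with mean correlations between arrays of 0.818 for Ha-RAS and control, 0.829 for Ki-RAS and control and 0.820 for Ha-RAS and Ki-RAS, and the correlation of fold changes was 0.488, 0.528 and 0.484 with control, Ha-RAS and Ki-RAS as the shared reference. The covariance of 0.638, above the highest simulated 0.0177, exceeds replicate noise in size. It does not speak to why the lines were equally far apart, since the simulated groups were unchanged. Their mean r was also 0.50, so correlations near it restate the distances. Fewer probes set the control apart (2766) than set Ha-RAS (3275) or Ki-RAS (3381) apart. Each of the 1946 probes called in all 3 comparisons counts for more than 1 line, so a common response of unequal size also counts for a RAS line. The counts thus do not decide on a common response as the largest part of the differences. Dim probes could account for part of the near equality, since the range of the 3 correlations of 0.0443 became 0.139 on probes detected on all 6 arrays, a filter that also leaves out transcripts absent from a line, and quantile normalization stays open with a range of 0.087 under a common median, against at most 0.0636 with any array left out. For changes of at least 8-fold a common response stays open, since 136 probes set the control apart against 112 and 88, but 51 against 51 and 24 with normexp fitted to the signals alone and 11 against 17 and 8 on probes detected on all 6 arrays. A candidate explanation for the equal distances is that each line diverged on its own apart from its RAS isoform, which cannot be told apart from an isoform effect with 1 line per isoform.

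Probes for 1 of several isoforms (suffix I) that were called between the RAS lines were mostly higher in Ha-RAS cells, 238 of 362 (65.75%), against 2787 of 5337 (52.22%) for probes of a single transcript (Fisher's exact test, two-sided, p = 5.03e-07, Benjamini-Hochberg adjusted p = 1.51e-06 over 3 comparisons). Against control the shares higher were 56.2% in Ha-RAS (exact p = 0.201, adjusted p = 0.201) and 42.9% in Ki-RAS cells (exact p = 0.00447, adjusted p = 0.0067), and on probes detected on all 6 arrays the Ki-RAS difference from single-transcript probes did not pass the threshold (exact p = 0.127) while that between the RAS lines did (60.19% against 50.73%, exact p = 0.00868). The low level of these probes is argued against by 10000 lists of single-transcript probes matched on level, whose highest share was 62.7%, and quantile normalization by cyclic loess, under which their share still exceeded that of single-transcript probes by 11.99 percentage points. The Fisher test treats probes as independent, and several probes of the same genes could carry the excess, which cannot be told apart here because 0 isoform-specific probe IDs were paired with a gene. A difference in isoform use between the lines may be a hypothesis worth following once the probes have gene names.

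More probes were detected in Ha-RAS cells alone (544) than in Ki-RAS (317) or control cells alone (322). Among those with a bound of at least 4-fold against both other lines the numbers were 61, 59 and 90, and among those called against both other lines 426, 309 and 316. A bound below 4-fold does not show that a difference is small, so these numbers do not decide between explanations. A higher sensitivity of the Ha-RAS arrays near the background was not borne out by the ratio of detected over undetected signal, which was 3.33 and 3.10 on the Ha-RAS arrays, 3.09 and 2.86 on the Ki-RAS arrays and 3.27 and 3.64 on the control arrays, but it is not excluded either, since detecting more dim probes can itself lower that ratio. It stays open together with weakly expressed transcripts specific to Ha-RAS cells, which were not tested.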
